A study of Homo sapiens with 48 samples.

How the data were processed

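RNA of H1 cells at passage 40 was extracted with Trizol, treated with DNase and amplified to biotin-labelled cRNA, per the labels' protocols. The arrays were Illumina HumanHT-12 bead arrays, going by the platform of the probe annotation. The deposited values are the authors' probe intensity on a linear scale, neither log-transformed nor scaled to a common distribution, as their medians show (63.4 to 111.7). BeadStudio is named in the submitters' processing notes, and its version and background settings are not given in the sources used here. No detection p-values and no scanner files were used here. Chip and position come from the array names in the titles. Titles give treatment, time, replicate and, after 0 h, medium. The 16 groups follow these and, at 0 h, the chip.

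Of 47321 probes, 14 had missing values on 12 to 24 of the arrays and were left out. Background was corrected with limma's normexp with an offset of 50, arrays were quantile normalized, values under 16 were set to 16, and log2 was taken. Probes were kept when above the array's median on at least 3 arrays, which 34117 were. The platform annotation gave 30106 probes 1 gene symbol and 8 several, and did not list 17193. Symbols were updated through the RefSeq gene table for 30067 probes, and 39 kept their older symbol. Probes with several symbols or none were not named. Each of the 16064 genes was read by its probe with the highest mean, and 4631 genes had more than 1 passing probe. Quantile normalization assumes that most genes keep their level, so values are relative to the other genes and a change of total RNA per cell is not measured. Normexp with an offset compresses changes of dim probes.

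One linear model with a mean for each of the 16 groups was fitted to all 48 arrays with limma 3.58.1 in R 4.3.3 (32 residual degrees of freedom, eBayes), so that groups share an estimate of the spread. The median residual SD was 0.111. There were 19 comparisons of 2 groups and 5 interactions, each adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05, and changes of at least 2-fold were counted separately. Tests used limma's moderated statistic, two-sided. Python 3.11.15 was used for the figures.

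The text names POU5F1, NANOG, SOX2, CDKN1A and MDM2, which did not pass where the report does not give them, except in 4 calls that single arrays decide and that stand with the effects of the alternatives, the first of the 10 largest rises and falls in order, and up to 4 members of a gene list by size of change among those that passed. Other genes are said to be chosen after their values were seen. The largest changes were taken among genes that passed, with the higher group's mean above the 60th percentile and, outside interactions, non-overlapping groups. The 15 lists covered pluripotency, TGF-beta/Nodal, FGF/ERK and BMP targets, p53 targets, S phase, G2/M, histones, neuroectoderm, primitive streak, endoderm, mesoderm, trophoblast/amnion, the ATF4 stress response and fibroblasts. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a comparison. Of 360 tests 170 passed, not all of which are described, and 148 of these also passed with an estimated correlation. List members without a named probe that passed the filter were not measured here and do not enter the counts. Design, groups, lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The normexp correction was chosen, and quantile normalization taken by a rule fixed before, after the scale of the values had been seen and before any fit. Lists of metallothioneins, cholesterol synthesis, heat shock, actin and smooth muscle, and interferon-stimulated genes were chosen after gene changes had been seen.

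Alternatives were no filter and a stricter filter on dim probes, upper-quartile centring, a floor of 64, the mean of a gene's probes, a replicate block, array weights, a trended robust prior, fits on only the groups compared or only their chips, leaving out each array, fry and camera with an estimated correlation. A setting without background correction was chosen after seeing the data. Simulations changed 50 genes at each size. For aphidicolin against DMSO at 96 h in differentiation medium, 14% of log2 changes of 0.25 and 84% of 0.5 passed. All of 1 and 2 did, with 5 false calls among 15864 unchanged genes. Its interaction with medium gave 8%, 56%, 100% and 100%, with 7 false calls. Camera gave 7 of 200 unchanged lists a p under 0.05. In the data lists can correlate and 7614 genes passed, so rates may differ.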

Results

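Gene expression was measured on 48 Illumina bead arrays in H1 cells, an established human embryonic stem cell line, in 16 groups of 3 arrays. Cells were kept either in mTeSR1, a medium that maintains pluripotency (pluripotency medium), or in medium without the growth factors bFGF and TGF-beta (differentiation medium), for 48 or 96 h. They received DMSO as vehicle, aphidicolin, an inhibitor of the replicative DNA polymerases, or aphidicolin together with AZD7762, an inhibitor of the checkpoint kinases CHK1 and CHK2. On its chips each medium had 2 starting groups at 0 h. Their titles say that they were pre-treated with DMSO or aphidicolin while another label gives no treatment, so the length of that exposure is unknown. The arrays lay on 4 chips of 12, the pluripotency set on chips 1 and 2 and the other on chips 3 and 4. Median raw intensity was 63.4 to 79.5 on chips 1 and 2 and 88.2 to 111.7 on chips 3 and 4. Replicate arrays of a group correlated at r of 0.993 to 0.997 across probes, which are not independent replicates. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision.

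Changes are log2 differences of normalised intensity ± SE from limma with n = 3 arrays per group, and genes said to rise, fall, be higher or be lower passed an adjusted p of 0.05 (Benjamini-Hochberg over 16064 genes). Adjusted p-values of gene lists are from camera with Benjamini-Hochberg, and list members not counted did not pass. Outside interactions, the genes named for the size of their change had all 3 arrays of one group above all 3 of the other, which chance gives in 10% of such splits. A value marked near background has a group mean under 6.75, the 60th percentile of all log2 values, where changes are compressed. A value marked probes differ belongs to a gene with another probe whose change had the opposite sign. Other probes with a much smaller change of the same sign are not marked.

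The first question was how H1 cells change when bFGF and TGF-beta are withdrawn. By 96 h in differentiation medium with DMSO, NANOG, a core pluripotency factor, had fallen (-2.58 ± 0.09, 5.97-fold lower, limma with Benjamini-Hochberg adjusted p = 1.8e-29), from 9.42 ± 0.11 to 6.84 ± 0.09 (SD, n = 3). POU5F1, which encodes OCT4, also fell (-1.09 ± 0.09), whereas SOX2, which neural progenitors keep, rose (0.78 ± 0.10), as did CDKN1A (0.95 ± 0.09), the p53-induced inhibitor of cyclin-dependent kinases also called p21. The largest rises were those of DLK1 (6.79 ± 0.09), an imprinted Notch-family ligand, CYP26A1 (5.78 ± 0.10), which degrades retinoic acid, and SOX21 (4.92 ± 0.09), a neural transcription factor. Next came LMO1 (4.53 ± 0.11, near background), FRZB (4.52 ± 0.08) and SIX3 (4.28 ± 0.09, near background), the last a forebrain homeobox gene, then PAMR1 (4.13 ± 0.09), FLRT3 (4.07 ± 0.10, near background), VWF (4.06 ± 0.09, near background) and GPC3 (4.02 ± 0.08). The largest falls were in metallothioneins, which bind zinc and copper, namely MT1G (-6.33 ± 0.10), MT1H (-5.87 ± 0.10, near background), MT2A (-4.86 ± 0.11) and MT1E (-4.70 ± 0.11), followed by the mitochondrial adenylate kinase AK4 (-4.12 ± 0.09) and neurotensin, NTS (-3.76 ± 0.13, near background).

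Gene lists fixed in advance moved as follows over the same 96 h. Of 20 pluripotency genes, 14 fell and 6 rose (same adjusted over the list alone), at a median of -0.81 (camera adjusted p = 4.4e-06). Among the falls were GDF3 (-2.26 ± 0.08, near background), L1TD1 (-1.85 ± 0.08) and FOXD3 (-1.27 ± 0.08, near background). Of 11 BMP targets, 10 rose and 0 fell (same adjusted over the list alone), at a median of 1.35 (camera adjusted p = 2.1e-09). The largest changes were those of ID2 (2.33 ± 0.09), SMAD6 (2.16 ± 0.09) and ID1 (2.11 ± 0.08). Of 18 neuroectoderm genes, 11 rose and 2 fell (11 up and 3 down adjusted over the list alone), at a median of 1.17 (camera adjusted p = 6.9e-07). Forebrain regulators among the rises were HESX1 (2.84 ± 0.10), RAX (2.10 ± 0.10, near background) and LHX5 (2.10 ± 0.08, near background). Of 14 FGF/ERK targets, 11 fell and 2 rose (same adjusted over the list alone), at a median of -0.56 (camera adjusted p = 3.3e-06). The feedback genes DUSP6 (-2.86 ± 0.11) and SPRY4 (-2.37 ± 0.08) and the transcription factor ETV4 (-2.16 ± 0.09) were lower. The immediate early gene EGR1 was higher (2.71 ± 0.08). Of 11 TGF-beta/Nodal targets, 6 fell and 2 rose (same adjusted over the list alone), at a median of -0.25 (camera adjusted p = 0.012). LEFTY1 (-2.54 ± 0.09, near background) and NODAL (-2.26 ± 0.08, near background) fell, while the activin antagonist FST rose (3.87 ± 0.07). Of 11 trophoblast/amnion genes, 6 rose and 2 fell (same adjusted over the list alone), at a median of 0.44 (camera adjusted p = 0.012). These included TFAP2C (2.03 ± 0.09) and GATA3 (1.16 ± 0.08, near background). Of 15 ATF4 stress-response genes, 13 rose and 0 fell (same adjusted over the list alone), at a median of 1.28 (camera adjusted p = 1.1e-10). Of 27 p53 targets, 16 rose and 2 fell (17 up and 2 down adjusted over the list alone), at a median of 0.32 (camera adjusted p = 0.00092). Of 56 G2/M genes, 26 fell and 10 rose (10 up and 27 down adjusted over the list alone), at a median of -0.16 (camera adjusted p = 0.04, and adjusted p = 0.11 with an estimated correlation). Of 9 primitive streak genes, 3 rose and 0 fell (2 up and 0 down adjusted over the list alone), at a median of 0.11 (camera adjusted p = 0.39). In all, 3574 of 16064 genes rose and 3528 fell, 461 and 290 of them at least 2-fold (limma, Benjamini-Hochberg). With upper-quartile centring in place of quantile normalization the counts were 2959 and 4256. The 0 h and 96 h arrays lay on different chips, so chip and time cannot be told apart in this comparison.

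At 48 h both groups lay on 1 chip. NANOG was lower (-0.38 ± 0.09), POU5F1 did not pass (0.14 ± 0.09) and PRDM14, a pluripotency regulator, was higher (1.65 ± 0.09). SOX2 was higher (0.76 ± 0.10) and CDKN1A lower (-0.35 ± 0.09). The largest rises were SOX21 (4.59 ± 0.09), DDIT4 (4.06 ± 0.15), GADD45G (3.56 ± 0.08), FGFR3 (3.25 ± 0.07, probes differ), INHBE (3.14 ± 0.17), CYP26A1 (3.01 ± 0.10), TRIB3 (2.87 ± 0.08) and CHAC1 (2.82 ± 0.15). DDIT4 restrains mTORC1, TRIB3 is a pseudokinase induced by ATF4, and CHAC1 degrades glutathione. The largest falls were MT2A (-3.56 ± 0.11), MT1H (-3.28 ± 0.10), VGF (-3.25 ± 0.08), AK4 (-3.07 ± 0.09) and DUSP6 (-3.05 ± 0.11), the last a phosphatase of ERK. The transcription factor ATF4 drives a stress response to amino acid shortage or unfolded protein. Among 15 ATF4 stress-response genes, 14 rose and 1 fell (same adjusted over the list alone), at a median of 1.40 (camera adjusted p = 4.4e-16). DDIT3, which encodes the stress factor CHOP, was among the rises (2.62 ± 0.16). Among 14 FGF/ERK targets, 8 fell and 2 rose (same adjusted over the list alone), at a median of -0.39 (camera adjusted p = 1.9e-05). The falls included DUSP5 (-2.30 ± 0.08), ETV4 (-2.03 ± 0.09) and ETV5 (-1.66 ± 0.08). Among 11 BMP targets, 5 rose and 0 fell (same adjusted over the list alone), at a median of 0.18 (camera adjusted p = 0.0019). ID1 changed most (2.46 ± 0.08). Among 20 pluripotency genes, 7 rose and 4 fell (8 up and 4 down adjusted over the list alone), at a median of 0.12 (camera adjusted p = 0.22). LEFTY1 (-2.29 ± 0.09) and NODAL (-2.09 ± 0.08, near background) were lower, but the TGF-beta/Nodal list was not called (3 up, 5 down, median -0.12, camera adjusted p = 0.22). Of 37 S-phase genes, 15 fell and 4 rose (same adjusted over the list alone), at a median of -0.14 (camera adjusted p = 0.0019, and adjusted p = 0.11 with an estimated correlation). RRM2 (-1.62 ± 0.09), a subunit of ribonucleotide reductase, and PCNA (-1.0 ± 0.10), the polymerase clamp, were lower. In all, 3433 of 16064 genes rose and 2840 fell, 274 and 129 of them at least 2-fold (limma, Benjamini-Hochberg). With upper-quartile centring 2767 rose and 3718 fell, a share of rises of 42.7% against 54.7%.

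**Figure D1:**
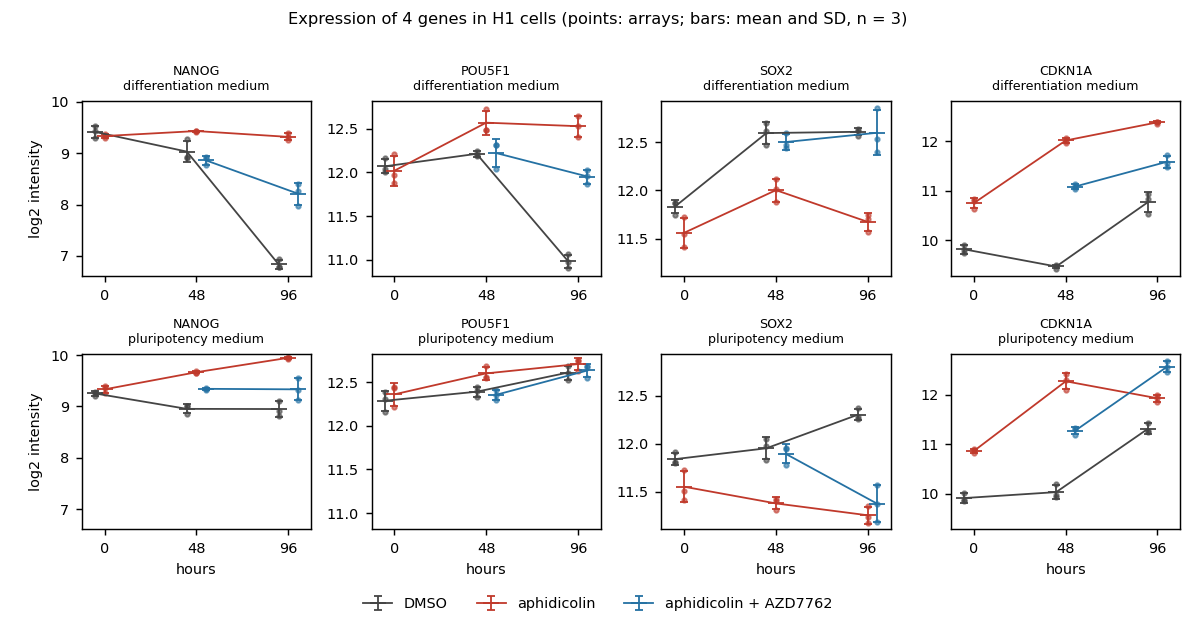
Normalised log2 intensity of NANOG, POU5F1, SOX2 and CDKN1A (columns) against hours in differentiation medium (upper panels) and pluripotency medium (lower panels), where points are arrays, bars are the mean and SD of 3 arrays, and DMSO is grey, aphidicolin red and aphidicolin with AZD7762 blue. At 96 h in differentiation medium NANOG was at 6.84 with DMSO, 8.21 with aphidicolin and AZD7762 and 9.31 with aphidicolin.

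Cells that stayed in pluripotency medium with DMSO served as the control for time in culture. NANOG was lower at 48 h (-0.30 ± 0.09) and 96 h (-0.30 ± 0.09), and POU5F1 (0.32 ± 0.09, probes differ) and SOX2 (0.46 ± 0.10) were higher at 96 h. CDKN1A rose by 96 h (1.40 ± 0.09). At 48 h the largest rises were NPTX1 (3.31 ± 0.13), DDIT4 (2.57 ± 0.15), STC1 (2.31 ± 0.08) and EFHD1 (2.09 ± 0.07), and the largest falls were MT1H (-3.74 ± 0.10), MT1E (-3.47 ± 0.11), MT1G (-3.32 ± 0.10), MT2A (-3.25 ± 0.11) and VGF (-3.15 ± 0.08). By 96 h the largest rises were TXNIP (3.17 ± 0.14), EFHD1 (2.98 ± 0.07), DDIT4 (2.77 ± 0.15), ACTN3 (2.71 ± 0.09) and FILIP1 (2.71 ± 0.08), TXNIP being a glucose-responsive inhibitor of thioredoxin. The largest falls were ANXA1 (-3.06 ± 0.10, near background), VGF (-2.94 ± 0.08), HAS3 (-2.91 ± 0.08) and TIMP4 (-2.83 ± 0.07). The ATF4 list was higher at both times, with 14 of 15 genes up and none down at 48 h (median 0.54, camera adjusted p = 2.9e-11) and 13 up and none down at 96 h (median 0.79, camera adjusted p = 1.9e-09), the same counts as adjusted over the list alone. At 96 h the replication genes were lower. Among 37 S-phase genes, 28 fell and 0 rose (same adjusted over the list alone), at a median of -0.37 (camera adjusted p = 7.3e-09). The falls included RRM2 (-1.52 ± 0.09), UHRF1 (-1.50 ± 0.07) and MCM5 (-1.29 ± 0.10). Of 14 histone genes, 10 fell and 2 rose (2 up and 11 down adjusted over the list alone), at a median of -0.48 (camera adjusted p = 0.00055). Among 27 p53 targets, 14 rose and 1 fell (14 up and 2 down adjusted over the list alone), at a median of 0.27 (camera adjusted p = 0.00055). The stress cytokine GDF15 was higher (2.13 ± 0.10). LEFTY1 was higher at 48 h (1.60 ± 0.09) and lower at 96 h (-1.77 ± 0.09) than at the start. FGF/ERK targets were lower in this medium too. At 48 h, for the 14 FGF/ERK targets, 6 fell and 0 rose (same adjusted over the list alone), at a median of -0.18 (camera adjusted p = 1.8e-06). At 96 h, of 14 FGF/ERK targets, 9 fell and 2 rose (same adjusted over the list alone), at a median of -0.37 (camera adjusted p = 0.00055). Among 11 TGF-beta/Nodal targets, 6 fell and 2 rose (same adjusted over the list alone), at a median of -0.42 (camera adjusted p = 0.0055). At 48 h that list was not called, with 5 up and 3 down, a median of -0.07 and a mean of 0.24 (camera adjusted p = 0.23). Other lists called at 48 h were histones (median -0.23, camera adjusted p = 0.0098), S phase (median -0.08, camera adjusted p = 0.037, and adjusted p = 0.21 with an estimated correlation), neuroectoderm (median -0.08, camera adjusted p = 0.025) and G2/M (median 0.09, camera adjusted p = 0.012, and adjusted p = 0.052 with an estimated correlation). At 48 h 2662 genes rose and 2091 fell (72 and 40 at least 2-fold) and at 96 h 3450 genes rose and 3381 fell (288 and 176 at least 2-fold), by limma with Benjamini-Hochberg, against 2163 and 2414 and 3044 and 3521 with upper-quartile centring. The 96 h comparison crosses chips. NANOG did not pass without DMSO replicate 1 of 48 h (-0.25) or of 96 h (-0.24), nor did POU5F1 at 96 h as the mean of its probes (0.13).

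Whether the change from 0 h differed between media was tested as an interaction, in which a positive value is a larger rise or smaller fall in differentiation medium. At 96 h it was negative for NANOG (-2.28 ± 0.13, limma with Benjamini-Hochberg adjusted p = 2.6e-20), POU5F1 (-1.41 ± 0.12, but -0.19 by its other probe) and CDKN1A (-0.45 ± 0.12). It was most positive for DLK1 (6.35 ± 0.12), PKDCC (5.0 ± 0.14), CYP26A1 (4.85 ± 0.14), FRZB (4.46 ± 0.11), LMO1 (4.44 ± 0.16, near background) and SIX3 (4.29 ± 0.12, near background). It was most negative for the metallothioneins MT1G (-6.76 ± 0.15), MT1H (-6.47 ± 0.15, near background), MT1E (-4.99 ± 0.16), MT2A (-4.87 ± 0.15) and MT1X (-4.33 ± 0.21), then the secreted hormone STC1 (-3.70 ± 0.12). Among 18 neuroectoderm genes, 11 were positive and 0 negative (same adjusted over the list alone), at a median of 1.29 (camera adjusted p = 1.2e-13). For the 11 BMP targets, 9 were positive and 0 negative (same adjusted over the list alone), at a median of 1.24 (camera adjusted p = 1.2e-11). For the 20 pluripotency genes, 10 were negative and 2 positive (3 positive and 10 negative adjusted over the list alone), at a median of -0.54 (camera adjusted p = 5.2e-07). For the 37 S-phase genes, 23 were positive and 2 negative (24 positive and 3 negative adjusted over the list alone), at a median of 0.36 (camera adjusted p = 1.4e-05). The median change of that list from 0 h was -0.03 in differentiation medium and -0.37 in pluripotency medium. At 48 h NANOG did not pass (-0.08 ± 0.13, probes differ), SOX2 was positive (0.65 ± 0.13) and CDKN1A negative (-0.47 ± 0.12). The most positive were SOX21 (3.99 ± 0.13), CYP26A1 (3.73 ± 0.14), FEZ1 (2.89 ± 0.11) and IRX2 (2.78 ± 0.14) and the most negative LEFTY1 (-3.89 ± 0.12), NTS (-3.65 ± 0.18), NPTX1 (-3.61 ± 0.19) and AK4 (-3.10 ± 0.12). For the 15 ATF4 stress-response genes, 10 were positive and 1 negative (11 positive and 1 negative adjusted over the list alone), at a median of 0.88 (camera adjusted p = 4.1e-09). Of 20 pluripotency genes, 10 were positive and 2 negative (same adjusted over the list alone), at a median of 0.28 (camera adjusted p = 0.0066). PRDM14 (2.11 ± 0.13) and SALL4 (0.71 ± 0.12) were positive and GDF3 was negative (-1.49 ± 0.11). At 96 h the ATF4 list had a median of 0.35 (camera adjusted p = 0.035, and adjusted p = 0.35 with an estimated correlation). No interaction was called for FGF/ERK targets at 48 h (median -0.05, camera adjusted p = 0.055) or 96 h (median -0.23, camera adjusted p = 0.12) or for TGF-beta/Nodal targets (median -0.05, camera adjusted p = 0.25, and median -0.14, camera adjusted p = 0.84). The interaction passed for 3136 genes at 48 h and 4485 at 96 h (limma, Benjamini-Hochberg). At 48 h 1661 were positive and 1475 negative, against 1279 and 1700 with upper-quartile centring. The 96 h interaction, unlike that at 48 h, crosses chips in each medium, so not even additive chip differences need cancel.

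The DMSO groups at 0 h, which lay on different chips, were compared between the sets to check their starting points. The differentiation set had 398 genes higher and 302 lower, 1 and 1 by at least 2-fold, namely ZNF264 (1.82 ± 0.18, near background) and ACTG1P4 (-1.07 ± 0.10), and no list was called. ZNF264 lay at 5.66, the lowest value in the data, on all 3 arrays of the pluripotency set. The total of 700 genes fell to 453, 318 and 303 without replicate 1, 2 or 3 of the pluripotency set and to 291, 362 and 408 without replicate 1, 2 or 3 of the differentiation set, and was 307 with a replicate block and 1218 with array weights.

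The arrays labelled as pre-treated addressed what aphidicolin had done before the medium was changed. CDKN1A was higher with aphidicolin in both sets, by 0.93 ± 0.09 in the differentiation set and 0.95 ± 0.09 in the pluripotency set (limma, Benjamini-Hochberg adjusted p = 1.1e-10 and 1.2e-10), or 1.91-fold and 1.93-fold. NACAD was higher to a similar extent (0.96 ± 0.09 and 0.94 ± 0.09), though its lowest probe gave 0.05 and 0.15. Histone genes were lower, with H2AC6 (-0.99 ± 0.10, near background), H2BC12 (-0.98 ± 0.11), H2BC5 (-0.97 ± 0.10) and H4C8 (-0.90 ± 0.08) in the differentiation set and H2BC12 (-1.09 ± 0.11), H2BC5 (-1.08 ± 0.10), H2AC6 (-1.0 ± 0.10, near background) and H4C8 (-0.82 ± 0.08) in the other. The BMP target ID2 was lower in both sets (-0.88 ± 0.09 and -0.78 ± 0.09), and the pluripotency-associated chromatin factor UTF1 was higher (0.73 ± 0.09 and 0.78 ± 0.09). Neither NANOG (-0.08 ± 0.09 and 0.08 ± 0.09) nor POU5F1 (-0.05 ± 0.09 and 0.07 ± 0.09) passed. In the differentiation set the lists gave these counts. Among 14 histone genes, 8 fell and 0 rose (0 up and 10 down adjusted over the list alone), at a median of -0.38 (camera adjusted p = 9.6e-21). Among 56 G2/M genes, 19 fell and 0 rose (1 up and 28 down adjusted over the list alone), at a median of -0.19 (camera adjusted p = 3.5e-17). NCAPD2 (-0.53 ± 0.09), a condensin subunit, and MKI67 (-0.48 ± 0.08), a proliferation marker, were lower. For the 27 p53 targets, 8 rose and 0 fell (12 up and 0 down adjusted over the list alone), at a median of 0.20 (camera adjusted p = 1.6e-07). GDF15 (0.50 ± 0.10) and PHLDA3 (0.48 ± 0.09) were higher. Of 9 fibroblast genes, 4 rose and 0 fell (4 up and 1 down adjusted over the list alone), at a median of 0.21 (camera adjusted p = 0.0065, and adjusted p = 0.056 with an estimated correlation). COL1A1 was higher by 0.50 ± 0.08 in this set and 0.50 ± 0.08 in the other. In the pluripotency set 9 of 14 histone genes (camera adjusted p = 1.2e-23) and 20 of 56 G2/M genes (camera adjusted p = 2e-18) fell and 10 of 27 p53 targets rose (camera adjusted p = 1.2e-06).

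At 0 h 901 genes rose and 341 fell (0 and 0 at least 2-fold) in the differentiation set and 907 genes rose and 351 fell (0 and 3 at least 2-fold) in the pluripotency set (limma, Benjamini-Hochberg). The sets, which share no arrays but may share cultures, called 572 of the same genes higher (50.9 expected for independent lists) and 174 lower (7.45 expected). In the differentiation set the total fell from 1242 to 727 without DMSO replicate 1, 744 without aphidicolin replicate 1 and 715 without aphidicolin replicate 2, and was 1955 with array weights. In the pluripotency set it fell from 1258 to 747 without DMSO replicate 1, 763 without aphidicolin replicate 1 747 without aphidicolin replicate 2 and 796 from only the groups compared, and with upper-quartile centring 662 rose and 414 fell, a share of rises of 61.5% against 72.1%.

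The central comparison addressed whether cells treated with aphidicolin leave the pluripotent state when the growth factors are withdrawn. At 96 h in differentiation medium, NANOG was 5.56-fold higher with aphidicolin than with DMSO (2.48 ± 0.09, limma with Benjamini-Hochberg adjusted p = 8.9e-29), at 9.31 ± 0.07 against 6.84 ± 0.09 (SD, n = 3). POU5F1 was 2.93-fold higher (1.55 ± 0.09), although its other probe gave 0.00 here and -0.25 over 96 h with DMSO. SOX2 was lower (-0.94 ± 0.10). CDKN1A was higher (1.62 ± 0.09), while MDM2, the ubiquitin ligase of p53 and a p53 target, did not pass (0.22 ± 0.12, probes differ). The largest rises were NTS (5.19 ± 0.13, near background), MT1X (4.39 ± 0.15), AK4 (4.14 ± 0.09), PDZD4 (4.12 ± 0.09), CLC (4.06 ± 0.10, near background), SYT4 (3.61 ± 0.08, near background), ANXA1 (3.55 ± 0.10) and GAL (3.38 ± 0.09). The largest falls were CYP26A1 (-5.17 ± 0.10), LMO1 (-4.47 ± 0.11, near background), DLK1 (-4.33 ± 0.09), SIX3 (-4.14 ± 0.09, near background), PKDCC (-4.06 ± 0.10), SOX21 (-3.83 ± 0.09), INHBE (-3.69 ± 0.17), VWF (-3.67 ± 0.09) and BARHL1 (-3.59 ± 0.10, near background).

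Among the lists at 96 h, markers of pluripotency and of Nodal and FGF signalling were higher with aphidicolin. Among 20 pluripotency genes, 16 rose and 4 fell (same adjusted over the list alone), at a median of 0.87 (camera adjusted p = 3.9e-07). The rises included GDF3 (3.27 ± 0.08, near background), UTF1 (2.10 ± 0.09) and DPPA2 (1.98 ± 0.09, near background). For the 11 TGF-beta/Nodal targets, 8 rose and 2 fell (same adjusted over the list alone), at a median of 0.73 (camera adjusted p = 0.00021). NODAL (3.21 ± 0.08, near background), LEFTY1 (3.11 ± 0.09, near background) and LEFTY2 (1.97 ± 0.08) rose and FST fell (-2.32 ± 0.07). Among 14 FGF/ERK targets, 12 rose and 1 fell (same adjusted over the list alone), at a median of 0.79 (camera adjusted p = 1.5e-07). The transcription factors ETV5 (2.3 ± 0.08) and ETV4 (2.16 ± 0.09) and the phosphatase DUSP6 (2.12 ± 0.11) were higher. Of 11 BMP targets, 9 fell and 1 rose (same adjusted over the list alone), at a median of -1.22 (camera adjusted p = 1.7e-07). The falls were led by ID2 (-3.41 ± 0.09), ID1 (-1.80 ± 0.08) and SMAD6 (-1.67 ± 0.09). For the 18 neuroectoderm genes, 10 fell and 2 rose (same adjusted over the list alone), at a median of -0.69 (camera adjusted p = 3.6e-05). HESX1 (-3.12 ± 0.10), LHX5 (-2.20 ± 0.08, near background) and RAX (-2.00 ± 0.10, near background) were lower. Of 15 ATF4 stress-response genes, 14 fell and 0 rose (same adjusted over the list alone), at a median of -1.40 (camera adjusted p = 1.1e-09). Among them were DDIT4 (-3.34 ± 0.15), DDIT3 (-2.94 ± 0.16) and TRIB3 (-2.53 ± 0.08) and asparagine synthetase, ASNS (-2.43 ± 0.09). Of 27 p53 targets, 17 rose and 2 fell (same adjusted over the list alone), at a median of 0.26 (camera adjusted p = 2.5e-05). PHLDA3 (1.75 ± 0.09), GDF15 (1.71 ± 0.10) and DDB2 (1.24 ± 0.08) were higher, DDB2 being a DNA repair factor. For the 14 histone genes, 9 rose and 2 fell (same adjusted over the list alone), at a median of 0.44 (camera adjusted p = 0.00077). H2BC5 (2.18 ± 0.10) and H2AJ (1.76 ± 0.09) were higher. Among 9 fibroblast genes, 6 rose and 0 fell (same adjusted over the list alone), at a median of 0.41 (camera adjusted p = 0.00048). COL1A1, a collagen chain, was higher (2.80 ± 0.08). In all, 3684 of 16064 genes rose and 3930 fell, 506 and 464 of them at least 2-fold (limma, Benjamini-Hochberg). The counts were 3958 and 3741 with upper-quartile centring.

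At 48 h in differentiation medium CDKN1A was 5.83-fold higher with aphidicolin (2.54 ± 0.09), NANOG (0.40 ± 0.09) and POU5F1 (0.36 ± 0.09) were higher and SOX2 was lower (-0.59 ± 0.10). The largest rises were NTS (3.86 ± 0.13), LEFTY1 (3.50 ± 0.09), AK4 (3.08 ± 0.09), CLC (3.00 ± 0.10, near background), ACTA1 (2.96 ± 0.11) and NODAL (2.93 ± 0.08, near background). The largest falls were INHBE (-5.19 ± 0.17), DDIT4 (-4.59 ± 0.15), CHAC1 (-3.50 ± 0.15, near background), TRIB3 (-3.49 ± 0.08), DDIT3 (-3.26 ± 0.16, near background), PCK2 (-3.21 ± 0.10) and SOX21 (-2.97 ± 0.09). Among 15 ATF4 stress-response genes, 13 fell and 1 rose (same adjusted over the list alone), at a median of -1.62 (camera adjusted p = 1.3e-17). For the 20 pluripotency genes, 9 fell and 7 rose (same adjusted over the list alone), at a median of -0.07 (camera adjusted p = 0.71). Among 27 p53 targets, 21 rose and 1 fell (22 up and 1 down adjusted over the list alone), at a median of 0.71 (camera adjusted p = 2.4e-12). PHLDA3 (1.64 ± 0.09) and SESN1 (1.24 ± 0.09) were higher and SESN2, which ATF4 also induces, was lower (-1.35 ± 0.10). Of 37 S-phase genes, 19 rose and 5 fell (22 up and 5 down adjusted over the list alone), at a median of 0.20 (camera adjusted p = 0.00057). The rises included RRM2 (1.83 ± 0.09), PCNA (1.42 ± 0.10) and TYMS (0.94 ± 0.09). Of 11 mesoderm genes, 5 rose and 0 fell (same adjusted over the list alone), at a median of 0.14 (camera adjusted p = 0.0027). TAGLN (1.82 ± 0.11) and ACTA2 (1.77 ± 0.10), both contractile genes, and the VEGF receptor KDR (1.07 ± 0.09, near background) were higher. For the 9 fibroblast genes, 5 rose and 0 fell (same adjusted over the list alone), at a median of 0.34 (camera adjusted p = 0.00057). For the 14 FGF/ERK targets, 8 rose and 2 fell (same adjusted over the list alone), at a median of 0.47 (camera adjusted p = 9e-04). DUSP6 was higher (1.79 ± 0.11). Of 11 TGF-beta/Nodal targets, 6 rose and 3 fell (same adjusted over the list alone), at a median of 0.43 (camera adjusted p = 0.0038). Among 11 BMP targets, 5 fell and 0 rose (same adjusted over the list alone), at a median of -0.14 (camera adjusted p = 0.0021). ID2 (-2.00 ± 0.09), ID1 (-1.68 ± 0.08) and ID3 (-1.56 ± 0.08) were lower. In all, 3036 of 16064 genes rose and 3481 fell, 215 and 254 of them at least 2-fold (limma, Benjamini-Hochberg).

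To follow the changes with DMSO in differentiation medium as a whole without shared arrays, genes that changed at least 2-fold over 96 h (461 up, 290 down) were followed in aphidicolin against DMSO at 48 h, and those that changed over 48 h (274 up, 129 down) at 96 h. The sets also hold changes seen in pluripotency medium with DMSO, namely 105 of the risen and 80 of the fallen genes over 96 h (8.26 and 3.18 expected for independent lists) and 38 and 28 over 48 h (1.23 and 0.321 expected). With aphidicolin they moved against their DMSO direction, with a signed median of -0.52 ± 0.01 at 48 h and -0.92 ± 0.04 at 96 h (SD, n = 3), and 82.3% and 84.4% of the genes did so. In camera with an estimated correlation, genes that had risen were lower (p = 1.6e-10 at 48 h and 9.9e-08 at 96 h) and genes that had fallen were higher (p = 2.1e-12 and 3.7e-12).

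**Figure D2:**
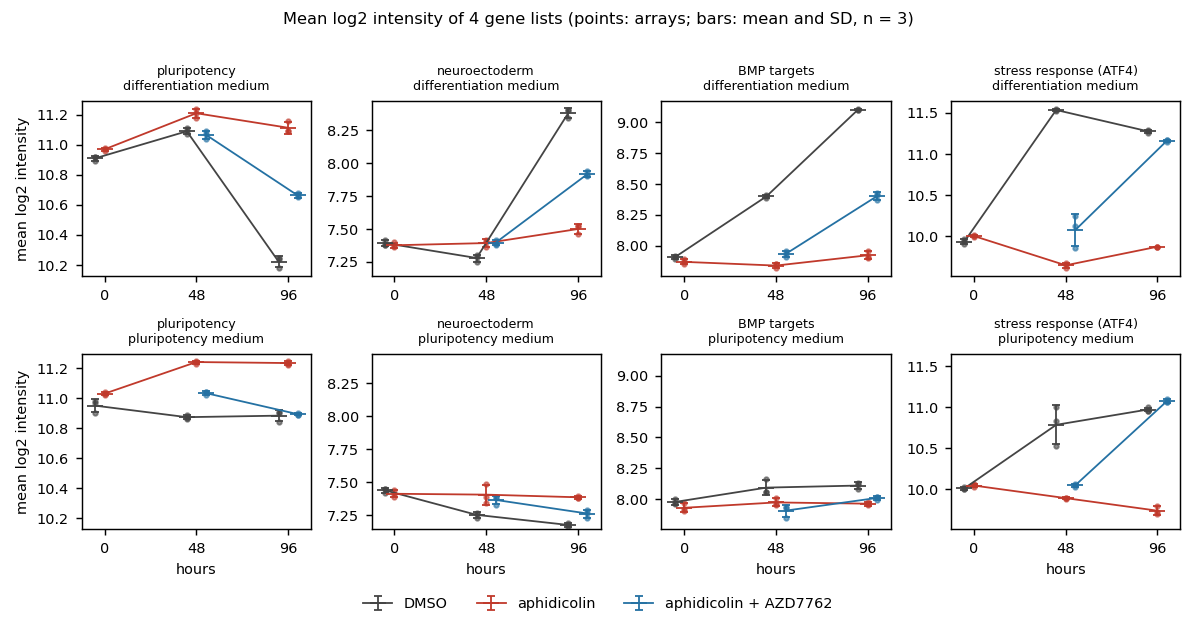
Mean log2 intensity of the measured genes of the pluripotency, neuroectoderm, BMP target and ATF4 stress-response lists (columns) against hours in differentiation medium (upper panels) and pluripotency medium (lower panels), where points are arrays, bars are the mean and SD of 3 arrays, and DMSO is grey, aphidicolin red and aphidicolin with AZD7762 blue. At 96 h in differentiation medium the ATF4 list was at 11.27 with DMSO, 9.87 with aphidicolin and 11.16 with aphidicolin and AZD7762.

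The same drug was then compared in pluripotency medium, where no factor was withdrawn. At 96 h NANOG was 1.99-fold higher with aphidicolin (1.00 ± 0.09), POU5F1 did not pass (0.10 ± 0.09), SOX2 was lower (-1.04 ± 0.10) and CDKN1A was higher (0.62 ± 0.09). The largest rises were CLC (4.13 ± 0.10), LEFTY1 (3.82 ± 0.09), NTS (3.65 ± 0.13), GDF3 (3.37 ± 0.08), NODAL (3.36 ± 0.08) and ANXA1 (3.18 ± 0.10, near background). The largest falls were again metallothioneins, MT1H (-5.14 ± 0.10), MT1G (-4.94 ± 0.10), MT1E (-4.52 ± 0.11, probes differ), MT2A (-4.33 ± 0.11) and MT1F (-3.73 ± 0.09), then CUZD1 (-3.72 ± 0.10), CTCFL (-3.38 ± 0.10, near background) and DDIT4 (-3.16 ± 0.15). For the 15 ATF4 stress-response genes, 13 fell and 0 rose (same adjusted over the list alone), at a median of -1.11 (camera adjusted p = 3.5e-10). Among 11 TGF-beta/Nodal targets, 8 rose and 2 fell (same adjusted over the list alone), at a median of 0.36 (camera adjusted p = 1.3e-05). The feedback inhibitor SMAD7 was higher (2.22 ± 0.09). Among 37 S-phase genes, 26 rose and 1 fell (27 up and 1 down adjusted over the list alone), at a median of 0.38 (camera adjusted p = 7.6e-07). RRM2 (1.59 ± 0.09) and the helicase HELLS (1.38 ± 0.11) were higher. For the 56 G2/M genes, 26 fell and 9 rose (9 up and 27 down adjusted over the list alone), at a median of -0.17 (camera adjusted p = 0.0064). The spindle checkpoint kinase BUB1 was lower (-1.05 ± 0.10). Of 7 endoderm genes, 4 rose and 0 fell (same adjusted over the list alone), at a median of 0.21 (camera adjusted p = 0.012). AFP, the alpha-fetoprotein gene, was higher (2.47 ± 0.08). Of 9 fibroblast genes, 7 rose and 0 fell (same adjusted over the list alone), at a median of 0.40 (camera adjusted p = 0.001). At 48 h CDKN1A was 4.72-fold higher (2.24 ± 0.09), and NANOG (0.72 ± 0.09) and MDM2 (0.58 ± 0.12) were higher and SOX2 was lower (-0.58 ± 0.10). Besides CDKN1A, the largest rises at 48 h were CLC (2.53 ± 0.10), ACTA1 (2.22 ± 0.11), TIMP4 (2.20 ± 0.07) and ABCA1 (2.19 ± 0.08), and the largest falls were NPTX1 (-3.49 ± 0.13), DDIT4 (-3.04 ± 0.15), INHBE (-2.57 ± 0.17) and CUZD1 (-2.13 ± 0.10). Of 15 ATF4 stress-response genes, 13 fell and 0 rose (same adjusted over the list alone), at a median of -0.59 (camera adjusted p = 1.7e-11). For the 27 p53 targets, 21 rose and 1 fell (22 up and 1 down adjusted over the list alone), at a median of 0.51 (camera adjusted p = 5.7e-13). Of 20 pluripotency genes, 11 rose and 3 fell (12 up and 4 down adjusted over the list alone), at a median of 0.24 (camera adjusted p = 0.00047). UTF1 changed most (1.81 ± 0.09). Of 56 G2/M genes, 32 fell and 3 rose (3 up and 34 down adjusted over the list alone), at a median of -0.28 (camera adjusted p = 5.2e-08). At 48 h 2671 genes rose and 2681 fell (137 and 83 at least 2-fold) and at 96 h 3631 genes rose and 3703 fell (366 and 360 at least 2-fold) (limma, Benjamini-Hochberg). With upper-quartile centring the counts at 48 h were 2542 and 2333.

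Between the media, which share no arrays, aphidicolin called 84 of the same genes at least 2-fold higher at 48 h (1.83 expected for independent lists) and 44 lower (1.31 expected). At 96 h it called 203 higher (11.5 expected) and 179 lower (10.4 expected). The difference of the aphidicolin effect between media was tested as an interaction, positive where the effect was higher in differentiation medium. At 96 h it was positive for NANOG (1.48 ± 0.13), POU5F1 (1.45 ± 0.12, probes differ) and CDKN1A (1.00 ± 0.12), and SOX2 did not pass (0.11 ± 0.13). The most positive were MT1G (7.83 ± 0.15), MT1H (7.67 ± 0.15, near background), MT2A (6.20 ± 0.15), MT1E (5.93 ± 0.16, probes differ) and STC1 (4.36 ± 0.12). The most negative were DLK1 (-4.98 ± 0.12), LMO1 (-4.49 ± 0.16, near background), SHISA2 (-4.27 ± 0.11), SIX3 (-4.24 ± 0.12, near background), VWF (-4.10 ± 0.12, near background), PKDCC (-4.02 ± 0.14) and CYP26A1 (-3.77 ± 0.14). Of 18 neuroectoderm genes, 12 were negative and 1 positive (same adjusted over the list alone), at a median of -0.96 (camera adjusted p = 5.3e-12). For the 11 BMP targets, 9 were negative and 0 positive (same adjusted over the list alone), at a median of -1.11 (camera adjusted p = 5.3e-12). Among 20 pluripotency genes, 11 were positive and 2 negative (same adjusted over the list alone), at a median of 0.43 (camera adjusted p = 1e-06). At 48 h the most positive were NPTX1 (4.44 ± 0.19), STC1 (3.43 ± 0.12), NTS (3.06 ± 0.18) and LEFTY1 (3.04 ± 0.12) and the most negative TRIB3 (-3.13 ± 0.12), ATF5 (-3.10 ± 0.16), SOCS2 (-2.86 ± 0.12) and CYP26A1 (-2.73 ± 0.14). Among 15 ATF4 stress-response genes, 10 were negative and 1 positive (1 positive and 12 negative adjusted over the list alone), at a median of -1.07 (camera adjusted p = 1.1e-13). Among 56 G2/M genes, 19 were positive and 0 negative (23 positive and 0 negative adjusted over the list alone), at a median of 0.24 (camera adjusted p = 1.9e-08). The interaction passed for 2868 genes at 48 h and 4244 at 96 h (limma, Benjamini-Hochberg).

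AZD7762 was never given alone, so its own effect cannot be told from undoing that of aphidicolin. At 96 h in differentiation medium, NANOG was lower with aphidicolin and AZD7762 than with aphidicolin (-1.10 ± 0.09, limma with Benjamini-Hochberg adjusted p = 1.3e-14), at 8.21 ± 0.21 against 9.31 ± 0.07 (SD, n = 3). POU5F1 (-0.58 ± 0.09, probes differ) and CDKN1A (-0.80 ± 0.09) were lower too and SOX2 was higher (0.93 ± 0.10). Rises were largest for CYP26A1 (4.76 ± 0.10), SOX21 (3.66 ± 0.09), INHBE (3.39 ± 0.17), PKDCC (3.12 ± 0.10), DDIT4 (3.08 ± 0.15), FILIP1 (2.89 ± 0.08), HESX1 (2.85 ± 0.10) and FGFR3 (2.79 ± 0.07). Falls were largest for NTS (-4.25 ± 0.13), MT1X (-4.07 ± 0.15), CLC (-3.92 ± 0.10, near background), AK4 (-3.35 ± 0.09, probes differ), LEFTY1 (-3.19 ± 0.09, near background), LMO3 (-2.95 ± 0.07, near background), GDF3 (-2.85 ± 0.08, near background) and NODAL (-2.83 ± 0.08, near background). For the 20 pluripotency genes, 12 fell and 4 rose (4 up and 13 down adjusted over the list alone), at a median of -0.37 (camera adjusted p = 0.00038). For the 11 TGF-beta/Nodal targets, 8 fell and 3 rose (same adjusted over the list alone), at a median of -0.47 (camera adjusted p = 0.00016). Of 11 BMP targets, 6 rose and 1 fell (6 up and 2 down adjusted over the list alone), at a median of 0.40 (camera adjusted p = 0.003). ID2 was higher (2.06 ± 0.09). For the 15 ATF4 stress-response genes, 14 rose and 1 fell (same adjusted over the list alone), at a median of 1.18 (camera adjusted p = 1.9e-13). DDIT3 (2.62 ± 0.16), TRIB3 (2.55 ± 0.08) and ASNS (2.33 ± 0.09) were higher. Of 14 histone genes, 11 fell and 0 rose (same adjusted over the list alone), at a median of -0.56 (camera adjusted p = 2.8e-09). H2BC5 (-2.72 ± 0.10), H2BC12 (-2.44 ± 0.11) and H4C8 (-1.79 ± 0.08) were lower. Among 18 neuroectoderm genes, 6 rose and 3 fell (7 up and 4 down adjusted over the list alone), at a median of 0.05 (camera adjusted p = 0.021). SIX3 (2.42 ± 0.09, near background) and POU3F1 (1.28 ± 0.09), both neural transcription factors, were higher. Of 27 p53 targets, 13 fell and 3 rose (same adjusted over the list alone), at a median of -0.24 (camera adjusted p = 0.015, and adjusted p = 0.078 with an estimated correlation). Of 14 FGF/ERK targets, 8 fell and 2 rose (same adjusted over the list alone), at a median of -0.37 (camera adjusted p = 0.0083, and adjusted p = 0.097 with an estimated correlation). EGR1 was higher (2.05 ± 0.08) and DUSP6 was lower (-1.71 ± 0.11). Among 9 fibroblast genes, 5 fell and 0 rose (same adjusted over the list alone), at a median of -0.63 (camera adjusted p = 0.00088). In all, 3115 of 16064 genes rose and 2994 fell, 213 and 247 of them at least 2-fold (limma, Benjamini-Hochberg). With upper-quartile centring 3057 rose and 4588 fell, a share of rises of 40% against 51%.

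At 48 h in differentiation medium CDKN1A (-0.93 ± 0.09), NANOG (-0.57 ± 0.09) and POU5F1 (-0.35 ± 0.09) were lower when AZD7762 was added and SOX2 was higher (0.50 ± 0.10). Rises were largest for DDIT4 (1.75 ± 0.15), INHBE (1.73 ± 0.17), SOX21 (1.57 ± 0.09) and GADD45G (1.43 ± 0.08). Falls were largest for CLC (-2.22 ± 0.10), LEFTY1 (-1.99 ± 0.09), DUSP6 (-1.76 ± 0.11), ETV5 (-1.73 ± 0.08) and ACTA1 (-1.68 ± 0.11). Among 14 FGF/ERK targets, 11 fell and 0 rose (0 up and 12 down adjusted over the list alone), at a median of -0.44 (camera adjusted p = 6e-20). Among 27 p53 targets, 12 fell and 0 rose (1 up and 15 down adjusted over the list alone), at a median of -0.25 (camera adjusted p = 3.5e-09). Of 15 ATF4 stress-response genes, 8 rose and 0 fell (10 up and 0 down adjusted over the list alone), at a median of 0.28 (camera adjusted p = 1.6e-06). Among 11 mesoderm genes, 4 fell and 0 rose (same adjusted over the list alone), at a median of -0.14 (camera adjusted p = 1.2e-05). The contractile genes ACTA2 (-1.20 ± 0.10) and TAGLN (-1.17 ± 0.11) were lower. For the 9 fibroblast genes, 3 fell and 0 rose (same adjusted over the list alone), at a median of -0.15 (camera adjusted p = 0.00063). In all, 1174 of 16064 genes rose and 1113 fell, 9 and 36 of them at least 2-fold (limma, Benjamini-Hochberg). The counts became 1763 and 1189 with upper-quartile centring. Falls outnumbered rises from only the groups compared (rises and falls of 875 and 924) and without aphidicolin replicate 1 (1037 and 1064) or 3 (904 and 927) or replicate 3 of the combination (885 and 945). The groups lay on different chips, so chip and drug cannot be told apart at 48 h. POU5F1 did not pass without replicate 1 of aphidicolin and AZD7762 (-0.26).

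Changes against the aphidicolin direction were also read without shared arrays. Genes that aphidicolin changed at least 2-fold in pluripotency medium were followed when AZD7762 was added in differentiation medium. With 137 risen and 83 fallen genes at 48 h the signed median was -0.57 ± 0.01, and with 366 and 360 genes at 96 h it was -0.75 ± 0.01 (SD, n = 3). Of these genes, 94.5% and 92.4% moved against their aphidicolin direction. By camera with an estimated correlation, those that had risen were lower (p = 1.8e-17 at 48 h and 1.9e-16 at 96 h) and those that had fallen were higher (p = 2e-12 and 7.8e-11).

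In pluripotency medium at 96 h, NANOG was lower (-0.61 ± 0.09) and CDKN1A higher (0.64 ± 0.09) when AZD7762 was added to aphidicolin, and neither POU5F1 (-0.07 ± 0.09) nor SOX2 (0.12 ± 0.10) passed. Rises were largest for MT1H (3.66 ± 0.10), INHBE (3.45 ± 0.17), DDIT4 (2.99 ± 0.15), MT1G (2.92 ± 0.10), ATF5 (2.72 ± 0.11), GDF15 (2.69 ± 0.10), ASNS (2.54 ± 0.09) and PCK2 (2.5 ± 0.10). Falls were largest for CLC (-2.92 ± 0.10), LEFTY1 (-2.83 ± 0.09), GDF3 (-2.20 ± 0.08), NTS (-2.11 ± 0.13) and LEFTY2 (-1.97 ± 0.08). Among 15 ATF4 stress-response genes, 13 rose and 0 fell (same adjusted over the list alone), at a median of 1.40 (camera adjusted p = 2.6e-20). Of 20 pluripotency genes, 9 fell and 0 rose (0 up and 10 down adjusted over the list alone), at a median of -0.17 (camera adjusted p = 2e-04). Among 14 histone genes, 10 fell and 1 rose (same adjusted over the list alone), at a median of -0.35 (camera adjusted p = 1.4e-06). For the 27 p53 targets, 14 rose and 2 fell (same adjusted over the list alone), at a median of 0.23 (camera adjusted p = 0.00014). SESN2 was higher (1.08 ± 0.10). At 48 h, across chips, CDKN1A (-1.0 ± 0.09) and NANOG (-0.32 ± 0.09) were lower and SOX2 was higher (0.52 ± 0.10). The largest rise was that of NPTX1 (2.84 ± 0.13) and the largest falls were CLC (-2.15 ± 0.10), H2BC12 (-1.59 ± 0.11) and ACTA1 (-1.39 ± 0.11). Of 27 p53 targets, 13 fell and 1 rose (1 up and 16 down adjusted over the list alone), at a median of -0.28 (camera adjusted p = 2.4e-08). Among 20 pluripotency genes, 10 fell and 2 rose (3 up and 10 down adjusted over the list alone), at a median of -0.22 (camera adjusted p = 0.00042). At 48 h 1211 genes rose and 1528 fell (7 and 19 at least 2-fold) and at 96 h 2637 genes rose and 2483 fell (107 and 96 at least 2-fold) (limma, Benjamini-Hochberg), the latter against 2563 and 2831 with upper-quartile centring. Between media at 96 h, AZD7762 called 55 of the same genes at least 2-fold higher (1.42 expected for independent lists) and 60 lower (1.48 expected).

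The interaction of AZD7762 with medium at 96 h was positive where its effect was higher in differentiation medium. It was negative for CDKN1A (-1.44 ± 0.12), NANOG (-0.49 ± 0.13) and POU5F1 (-0.50 ± 0.12, probes differ) and positive for SOX2 (0.81 ± 0.13). The most positive were CYP26A1 (4.30 ± 0.14), FRZB (3.44 ± 0.11), SOX21 (3.43 ± 0.13), HESX1 (3.17 ± 0.14) and PKDCC (3.00 ± 0.14). The most negative were MT1H (-6.05 ± 0.15, near background, probes differ), MT1G (-5.68 ± 0.15), MT2A (-3.52 ± 0.15), MT1E (-3.41 ± 0.16, probes differ) and MT1X (-3.00 ± 0.21). Among 27 p53 targets, 15 were negative and 0 positive (0 positive and 16 negative adjusted over the list alone), at a median of -0.36 (camera adjusted p = 4.6e-11). For the 18 neuroectoderm genes, 8 were positive and 1 negative (8 positive and 2 negative adjusted over the list alone), at a median of 0.09 (camera adjusted p = 1.5e-05). The interaction passed for 2457 genes (limma, Benjamini-Hochberg). As the mean of its probes POU5F1 did not pass (-0.20).

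Aphidicolin with AZD7762 was also set against DMSO, to see how far the combination lay from cells without either drug. At 96 h in differentiation medium NANOG (1.37 ± 0.09), POU5F1 (0.97 ± 0.09, but 0.07 by its other probe) and CDKN1A (0.82 ± 0.09) were higher than with DMSO, and SOX2 did not pass (-0.01 ± 0.10). Rises were largest for CNMD (2.34 ± 0.09), IDO1 (2.15 ± 0.07), COL1A1 (1.94 ± 0.08), PDZD4 (1.71 ± 0.09) and GDF15 (1.68 ± 0.10), IDO1 being a tryptophan-degrading enzyme. Falls were largest for DLK1 (-3.29 ± 0.09), DLX5 (-2.71 ± 0.09), BARHL1 (-2.53 ± 0.10), TSPAN18 (-2.09 ± 0.08) and LMX1A (-1.95 ± 0.10), among them the homeobox genes DLX5, BARHL1 and LMX1A. For the 20 pluripotency genes, 14 rose and 2 fell (15 up and 3 down adjusted over the list alone), at a median of 0.43 (camera adjusted p = 2.9e-10). For the 27 p53 targets, 14 rose and 0 fell (15 up and 0 down adjusted over the list alone), at a median of 0.27 (camera adjusted p = 4.5e-07). Among 11 BMP targets, 8 fell and 0 rose (0 up and 9 down adjusted over the list alone), at a median of -0.54 (camera adjusted p = 3e-13). Of 18 neuroectoderm genes, 9 fell and 2 rose (2 up and 10 down adjusted over the list alone), at a median of -0.25 (camera adjusted p = 3.5e-07). SIX3 (-1.72 ± 0.09), PAX6 (-1.26 ± 0.10) and CDH2 (-1.04 ± 0.07) were lower. For the 15 ATF4 stress-response genes, 0 rose and 0 fell (same adjusted over the list alone), at a median of -0.11 (camera adjusted p = 0.28). At 48 h, across chips, CDKN1A was higher (1.61 ± 0.09). Rises were largest for NTS (2.59 ± 0.13), NPTX1 (2.3 ± 0.13, probes differ), HSPA1B (1.96 ± 0.09) and STC1 (1.86 ± 0.08), and the largest falls were TRIB3 (-3.59 ± 0.08), INHBE (-3.46 ± 0.17), DDIT4 (-2.84 ± 0.15) and TSC22D3 (-2.75 ± 0.10). Of 15 ATF4 stress-response genes, 14 fell and 1 rose (same adjusted over the list alone), at a median of -1.56 (camera adjusted p = 1.1e-21). At 48 h 2306 genes rose and 2685 fell (51 and 115 at least 2-fold) and at 96 h 1817 genes rose and 1958 fell (51 and 67 at least 2-fold) (limma, Benjamini-Hochberg). With upper-quartile centring the counts at 48 h became 2960 and 2469.

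In pluripotency medium at 96 h, the combination against DMSO gave higher CDKN1A (1.25 ± 0.09) and NANOG (0.38 ± 0.09) and lower SOX2 (-0.92 ± 0.10). The largest rises were the contractile genes ACTA1 (2.83 ± 0.11) and TAGLN (2.34 ± 0.11), then NODAL (2.09 ± 0.08) and ACTG2 (2.04 ± 0.09). Falls were largest for MT2A (-2.84 ± 0.11), MT1E (-2.60 ± 0.11), SOX21 (-2.45 ± 0.09) and CUZD1 (-2.28 ± 0.10). Of 27 p53 targets, 19 rose and 0 fell (same adjusted over the list alone), at a median of 0.47 (camera adjusted p = 1.1e-15). For the 14 FGF/ERK targets, 9 rose and 1 fell (10 up and 1 down adjusted over the list alone), at a median of 0.56 (camera adjusted p = 3.1e-10). Of 9 fibroblast genes, 5 rose and 0 fell (same adjusted over the list alone), at a median of 0.65 (camera adjusted p = 2.2e-05). COL1A1 was higher (1.62 ± 0.08). At 48 h, across chips, NANOG was higher (0.39 ± 0.09). ZNF264 (1.81 ± 0.18, near background) is not ranked, since it lay near the lowest value in the data with DMSO (5.81 ± 0.21, SD) and differed as much between the 0 h sets. The largest other rises were ABCA1 (1.47 ± 0.08), NNAT (1.28 ± 0.08) and CDKN1A (1.24 ± 0.09), and the largest falls were DDIT4 (-2.20 ± 0.15), CHAC1 (-1.81 ± 0.15) and INHBE (-1.74 ± 0.17). Among 15 ATF4 stress-response genes, 13 fell and 0 rose (same adjusted over the list alone), at a median of -0.60 (camera adjusted p = 5.8e-17). Among 27 p53 targets, 14 rose and 1 fell (16 up and 1 down adjusted over the list alone), at a median of 0.24 (camera adjusted p = 1.2e-10). At 48 h 1289 genes rose and 1519 fell (13 and 19 at least 2-fold) and at 96 h 2262 genes rose and 2214 fell (81 and 67 at least 2-fold) (limma, Benjamini-Hochberg), the latter against 1957 and 2236 with upper-quartile centring.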

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

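Chosen only after the result was seen were both comparisons of the ATF4 list with its starting level, the 3 tests on metallothioneins and the splits that keep each array in its medium. The results here are differences between media in the effect of a drug or of time, tested as interactions, positive where the effect was higher in differentiation medium.

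The effect of aphidicolin differed between media for 2868 genes at 48 h and 4244 at 96 h, that of AZD7762 for 2457 genes at 96 h, and the change from 0 h with DMSO for 3136 genes at 48 h and 4485 at 96 h, the last across chips (limma, Benjamini-Hochberg). Regrouping the arrays does not decide on chance for these counts, since the splits carry the effects of medium, treatment or time. Of 100 splits, real one included, 9 gave as many genes for aphidicolin at 48 h (highest other 5275), 7 at 96 h (6053), 12 for AZD7762 (4315), 5 for the medium at 48 h (4252) and 12 at 96 h (5762). Each of the other splits as large, numbering 8, 6, 11, 4 and 11, followed the medium, or the treatment or time, more than the interaction, which points to the structure of the samples. With arrays kept in their medium the splits as large numbered 14, 12, 13, 9 and 11 of 100 (highest others 5315, 8649, 5003, 4869 and 5892), and each other split mixes treatments or times within a medium.

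For the 19 comparisons of 2 groups of 3 arrays the 10 splits are too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The highest other split called 0 genes for DMSO over 48 h in differentiation medium (6273), DMSO over 96 h in differentiation medium (7102), DMSO over 48 h in pluripotency medium (4753), aphidicolin at 0 h in the differentiation set (1242), aphidicolin at 96 h in pluripotency medium (7334) and the 0 h DMSO groups (700). It called 1 gene for aphidicolin at 96 h in differentiation medium (7614), the combination at 48 h in differentiation medium (4991), the combination at 96 h in differentiation medium (3775) and the combination at 48 h in pluripotency medium (2808) and 2 genes for DMSO over 96 h in pluripotency medium (6831), aphidicolin at 48 h in differentiation medium (6517), AZD7762 at 48 h in differentiation medium (2287), aphidicolin at 0 h in the pluripotency set (1258), aphidicolin at 48 h in pluripotency medium (5352) and AZD7762 at 96 h in pluripotency medium (5120). It called 5 for AZD7762 at 96 h in differentiation medium (6109), 13 for AZD7762 at 48 h in pluripotency medium (2739) and 19 for the combination at 96 h in pluripotency medium (4476). The numbers in brackets are the genes of the real split.

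Lists whose aphidicolin effect differed between media at 48 h had medians of -0.30 for pluripotency, -0.19 for BMP targets, 0.14 for S phase (adjusted p = 0.19 with an estimated correlation), 0.24 for G2/M and -1.07 for the ATF4 response. At 96 h the medians were 0.43 for pluripotency, 0.44 for FGF/ERK targets (adjusted p = 0.14 with an estimated correlation), -1.11 for BMP targets, 0.05 for p53 targets (adjusted p = 0.14 with an estimated correlation), -0.46 for S phase, 0.18 for G2/M and -0.96 for neuroectoderm, and 5.02 for metallothioneins. Single genes at 96 h were POU5F1 (1.45), NANOG (1.48) and CDKN1A (1.00). For AZD7762 at 96 h the medians were -0.29 for FGF/ERK targets (adjusted p = 0.083 with an estimated correlation), 0.08 for BMP targets, -0.36 for p53 targets, 0.36 for S phase, 0.14 for G2/M (adjusted p = 0.09 with an estimated correlation), -0.31 for histones, 0.09 for neuroectoderm and -0.41 for fibroblast. The genes were POU5F1 (-0.50), NANOG (-0.49), SOX2 (0.81) and CDKN1A (-1.44). For the change from 0 h to 48 h the medians were 0.28 for pluripotency, 0.11 for BMP targets, -0.18 for G2/M and 0.88 for the ATF4 response, with SOX2 at 0.65 and CDKN1A at -0.47. To 96 h they were -0.54 for pluripotency, 1.24 for BMP targets, 0.36 for S phase, -0.22 for G2/M, 1.29 for neuroectoderm and 0.35 for the ATF4 response (adjusted p = 0.35 with an estimated correlation), with POU5F1 at -1.41, NANOG at -2.28 and CDKN1A at -0.45.

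ATF4-list genes were lower with aphidicolin than with DMSO at 48 h in differentiation medium, with a median of -1.62 ± 0.02 (SE). Normalization as the cause is argued against by the median of -1.51 ± 0.03 with upper-quartile centring. With DMSO the list had risen by 1.40 ± 0.02 from 0 h, and with aphidicolin it ended at -0.34 ± 0.02 against its own 0 h group and -0.22 ± 0.02 against DMSO at 0 h. The last value argues against a fall below the starting level as the whole difference. Whether aphidicolin caused the slight fall stays open, since -0.34 lies between the bounds set. Of 15 genes, 13 lay below aphidicolin and 6 above DMSO at 0 h. An effect of aphidicolin on the stress response remains a hypothesis.

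Metallothionein genes were higher with aphidicolin in differentiation medium (1.64 ± 0.09) and lower in pluripotency medium (-4.03 ± 0.09) at 96 h, as list medians with SE. A shift of a whole chip is argued against, since each value compares arrays within 1 chip. Also argued against is 1 transcript read by all these probes. In pluripotency medium MT1X went from 13.34 with DMSO to 13.71 with aphidicolin while MT1E, MT1F, MT1G and MT2A fell. The change of MT1X exceeded their median by 4.79 ± 0.25 (SE). For those 4 genes, 1 transcript read by all their probes stays open. The 5 genes above background in all 4 groups had interactions of 5.93 (MT1E), 4.11 (MT1F), 7.83 (MT1G), 4.02 (MT1X) and 6.20 (MT2A), SD 1.59. With DMSO those 4 lay at 6.83 to 7.77 in differentiation medium, where changes are compressed, and at 11.59 to 13.58 in pluripotency medium. The opposite effects start from unequal DMSO levels, and their cause stays open.

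AZD7762 moved p53 targets apart in the media at 96 h, with a median interaction of -0.36 ± 0.02 (SE) and 24 of 27 genes below 0. Genes that ATF4 also induces are argued against as the whole cause, since without 6 of them the median was -0.36 ± 0.03. So is the choice of scaling (-0.35 ± 0.03, upper-quartile centring). What remains is a hypothesis, that the effect of AZD7762 on these genes may depend on the medium.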

How the results depend on the processing

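Of the alternatives only the setting without background correction was chosen after the data were seen, and the normexp correction of all others after the scale of the values was seen. No value of a named gene that passed, and no signed median of a gene set, changed sign under any setting run. The excess of rises or of falls among called genes turned with upper-quartile centring in 10 of 19 comparisons of 2 groups and 3 of 5 interactions. With the mean of a gene's probes it turned in 5 of the 19, with a stricter filter in 2, from only the groups compared in 2, and without the filter and with array weights in 1 each. Leaving out 1 array turned it in 5. Of counts of called genes, 260 stayed within 1.5 times and 4 moved, all at 0 h. These were 1955 with array weights for aphidicolin in the differentiation set, 796 from only the groups compared in the pluripotency set, 1218 with array weights between the sets and 1 more with a replicate block. Leaving out 1 array gave 715 to 1241 for the differentiation set, 747 to 1362 for the pluripotency set and 291 to 453 between the sets. The arrays that moved these counts are named with the 0 h results. Calls of gene lists went from 170 to 273 with fry, which does not compare a list with other genes. The signed median of aphidicolin genes under AZD7762 at 48 h, -0.57 in the report, was -0.59 with upper-quartile centring, -0.54 with the mean of a gene's probes, -0.59 with array weights and -0.59 to -0.56 without 1 array. At 96 h it was -0.72 with the mean of a gene's probes and -0.76 to -0.72 without 1 array. For these results the cause was not tested. Of values for named genes, 4652 kept their direction and side of the threshold under other settings and 2929 without 1 array, and 10 and 17 no longer passed. MDM2 with aphidicolin at 96 h in differentiation medium passed from only the groups compared (0.22), and so did SOX2 with AZD7762 at 96 h in pluripotency medium as the mean of its probes (0.26). Not named in the report are 4 calls that single arrays decide. In differentiation medium with DMSO, MDM2 was higher at 48 h (0.33 ± 0.12), but not without replicate 1 or 2 of 0 h or 3 of 48 h (0.23, 0.32 and 0.20), and at 96 h (0.34 ± 0.12), but not without replicate 1 or 2 of 0 h or 1 or 3 of 96 h (0.24, 0.32, 0.30 and 0.31). With AZD7762 at 48 h in pluripotency medium, MDM2 was lower (-0.36 ± 0.12), but not without aphidicolin replicate 1 or 2 or replicate 2 or 3 of the combination (-0.36, -0.28, -0.31 and -0.31), nor was POU5F1 (-0.25 ± 0.09) without aphidicolin replicate 1 or replicate 2 or 3 of the combination (-0.20, -0.24 and -0.22). Each also missed the threshold under at least 1 other setting. With upper-quartile centring the median change of all genes over the comparisons was -0.097 to 0.049. Signal over background limits dim genes, whose median residual SD was 0.125 in the lowest quartile of level against 0.0986 in the highest.

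Replicate numbers did not pair arrays within a set: none of 54 same-number pairs had deviations correlated above 0.1 (-0.152 to 0.0891). Of 48 arrays, 9 correlated best with their own number. A replicate block moved by over 1.5 times only the 0 h count between sets (307 against 700), where pairing was not tested.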

Other observations

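The gene groups in this part were chosen only after gene changes had been seen, as was the test on interferon-stimulated genes. Values over 96 h with DMSO and for AZD7762 at 48 h cross chips. Actin and smooth-muscle genes, which build the contractile cytoskeleton, rose with aphidicolin at 48 h in differentiation medium. Of 13 actin and smooth-muscle genes, 11 rose and 0 fell (same adjusted over the list alone), at a median of 0.86 (camera adjusted p = 1.5e-12). They were also higher at 96 h (10 up, 1 down, median 0.81, camera adjusted p = 2.4e-06) and, in pluripotency medium, at 48 h (11 up, 1 down, median 0.60, camera adjusted p = 1.8e-11) and 96 h (11 up, 2 down, median 1.08, camera adjusted p = 1.4e-08). Adding AZD7762 lowered them in differentiation medium at 48 h (0 up, 9 down, median -0.69, camera adjusted p = 2.1e-21) and 96 h (1 up, 10 down, median -0.59, camera adjusted p = 3.8e-07). In pluripotency medium they were lower at 48 h (0 up, 11 down, median -0.49, camera adjusted p = 1.2e-16), and at 96 h the list was not called (5 up, 2 down, median 0.11, camera adjusted p = 0.38), with an interaction of AZD7762 with medium at 96 h (median -0.77, camera adjusted p = 5.2e-14).

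Cholesterol-synthesis genes, which are induced when sterols are scarce, fell over 96 h with DMSO in differentiation medium. Of 16 cholesterol-synthesis genes, 14 fell and 0 rose (same adjusted over the list alone), at a median of -0.94 (camera adjusted p = 3.5e-11). They were lower at 96 h in pluripotency medium too (median -0.48, camera adjusted p = 1.5e-06), after a rise at 48 h (median 0.32, camera adjusted p = 0.00049).

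Heat-shock genes, which encode chaperones, fell with DMSO in differentiation medium over 48 h (median -0.45, camera adjusted p = 4.4e-07) and 96 h (median -0.51, camera adjusted p = 9.7e-05), whereas in pluripotency medium they were lower at 48 h (0 up, 5 down, median -0.12, camera adjusted p = 0.02, and adjusted p = 0.068 with an estimated correlation) and higher at 96 h (10 up, 1 down, median 0.29, camera adjusted p = 0.0014), with a negative interaction at 96 h (median -0.62, camera adjusted p = 6.6e-11). Metallothioneins fell with DMSO at 48 h in differentiation (median -2.34, camera adjusted p = 1.4e-15) and pluripotency medium (median -2.87, camera adjusted p = 1.4e-23). At 96 h they were lower in differentiation medium (median -4.09, camera adjusted p = 3.1e-16), and in pluripotency medium the list was not called (5 up, 1 down, median 0.36, camera adjusted p = 0.18), with a negative interaction (median -4.60, camera adjusted p = 8e-24).

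IDO1 (2.15), MX1 (1.44) and HERC5 (1.33), genes interferon can induce, picked after seeing their values, were higher with aphidicolin and AZD7762 than with DMSO at 96 h in differentiation medium. An interferon response was tested on 26 other interferon-stimulated genes. Their median was 0.03 ± 0.03 (SE), 3 rose and 1 fell (camera adjusted p = 0.12). Changes of dim genes are compressed, so a response stays open.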
